A study of Drosophila melanogaster with 10 samples.

How the data were processed

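Samples were 10 single arrays of the Affymetrix Drosophila Genome design, each from laser-captured mushroom body neurons that expressed a dominant negative ecdysone receptor. Per the labels' protocols, RNA was linearly amplified in 2 rounds before biotin labelling. The authors summarised the probes of each array to probe set values with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no versions. The deposited values are on the log2 scale. RMA corrects background, normally equalises the distributions of the arrays and combines the probes of a set; which arrays were processed together is not given in the sources used here, and the medians of the deposited columns differ, from 4.31 to 4.44. No reads or counts underlie these values, and the number of arrays sets the precision.

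Samples were grouped by the age and replicate number in their descriptions: 6 arrays at 0 h and 3 at 5 h after puparium formation. For 1 array the title gives 5 h while the age label and the description give 0 h. It was left without a group, and both assignments were computed as alternatives. The arrays of y,w animals named in the series design were not analysed here. No 2 arrays held the same values throughout: the SD of the difference between 2 arrays was at least 0.17 on the log2 scale.

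The table held 14010 probe sets. Leaving out 44 Affymetrix controls left 13966 for testing. Gene names came from the platform annotation: 12443 probe sets had 1 gene symbol, 327 had several and 1196 had none, and no gene was named from a probe set with several. Updating through gene identifiers changed 0 symbols. The files name no genome build, so no coordinates are given. Of the probe sets past the threshold, 23 had no symbol or several.

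Ages were compared on the deposited log2 values, with no filter and no further normalization, by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all probe sets tested and a threshold of 0.05. A table of 25 gene lists was fixed before the data were examined, of which 24 had at least 3 measured genes. Each gene was represented by its probe set with the highest mean. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry (directional and mixed p) beside it, and members were adjusted over all probe sets and over the list alone. Names that matched no gene in the table used were Tor, verl, hdc and nos. Single measures per array were compared with a two-sided exact permutation test over the 84 ways to choose 3 of 9 arrays; the smallest p it can give is 0.012. The 3' bias of an array was taken as the difference between the 3' and 5' control probe sets of actin and GAPDH. Signal background was read from the 8 control probe sets for sequences foreign to the fly, with a median of 2.84 and a highest value of 3.73.

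Genes named in the text follow a rule fixed before the data were examined. It takes the 10 largest differences in each direction among probe sets past the threshold that have 1 symbol other than a bare CG number and no overlap between the ages, and the largest 2 CG-numbered genes per direction. It adds EcR and usp, and up to 4 members past the threshold in each list, or, where none passed, the 2 with the largest differences. Genes named outside it are said to be chosen after their values were seen.

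The same steps were tested on simulated data with the means and residual spread of the real probe sets, drawn independently of one another. For 5 h against 0 h over 13966 probe sets, limma recovered 38% of probe sets shifted by 0.5 on the log2 scale, 85% of those shifted by 1 and 98% of those shifted by 2, with 6 false calls among 159. With nothing changed it made 0 calls. A list shifted by 0.5 was recovered, and 0 unrelated lists were called. With members drawn independently, this did not test lists whose genes vary together, as the ubiquitin and proteasome genes did (estimated correlation 0.61).

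Alternatives fixed beforehand were both assignments of the array with conflicting labels, filters on dim probe sets, repeated quantile normalization, median centring, array weights, a trended and robust prior, an exact permutation test per probe set, stricter thresholds, the mean of a gene's probe sets, replicate blocks, each array left out, the 3' bias as a covariate, and the other list tests. Using only 0 h replicates 1 to 3, only replicates 4 to 6, or a term for this split were chosen after seeing the data.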

Results

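Gene expression was measured in mushroom body neurons of *Drosophila* pupae around the time at which these neurons begin to prune their larval axon branches. The mushroom body is a paired brain structure for olfactory learning, and pruning of its larval axons is triggered by the steroid hormone ecdysone through the receptor EcR and its partner usp. In all animals the OK107-GAL4 driver expressed a dominant negative form of EcR, which blocks signalling through the receptor, and a membrane-bound green fluorescent protein. Labelled neurons were laser-captured, and their RNA was amplified in 2 rounds and hybridised to 1 array per sample. There were 6 arrays at 0 h after puparium formation and 3 at 5 h. The labels of 1 further array name both ages, and it enters no comparison. Arrays of y,w animals, with which the series design compares these, were not analysed here, so the values show how expression differed with age under the dominant negative receptor, not which genes depend on EcR. The labels call the samples biological replicates and do not say how many animals each one pooled. An array gives no count of molecules, and the number of arrays limits the precision.

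EcR itself did not pass the test between the ages. Its brighter probe set read 5.23 ± 0.32 on the log2 scale at 0 h (SD, n = 6) and 5.10 ± 0.03 at 5 h (SD, n = 3), with an adjusted p of 0.70 in limma. Single arrays read from 4.81 to 5.09 in 0 h replicates 1 to 3, from 5.42 to 5.60 in 0 h replicates 4 to 6, and from 5.06 to 5.13 at 5 h. The direction turned with the 0 h arrays used: the log2 difference, 5 h minus 0 h, was 0.15 against replicates 1 to 3 (adjusted p = 0.49) and -0.41 against replicates 4 to 6, where it passed (adjusted p = 0.028). Its dimmer probe set read 4.59 ± 0.17 and 4.37 ± 0.28 (adjusted p = 0.48). Which part of the transcript these probe sets read is not known here, so they check neither the transgene nor the labels. The gene usp read 5.48 ± 0.20 at 0 h and 5.33 ± 0.14 at 5 h (adjusted p = 0.57).

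The arrays at 0 h fell into 2 sets of 3. Across probe sets, which are not independent replicates, replicates 1 to 3 correlated with one another at Pearson r of 0.989 to 0.991, and replicates 4 to 6 at 0.970 to 0.981. Between these sets r was 0.948 to 0.974. The 3 arrays at 5 h correlated at 0.990 to 0.995 with one another, at 0.978 to 0.986 with 0 h replicates 1 to 3, and at 0.949 to 0.973 with 0 h replicates 4 to 6. The labels name no batch that matches this split. The 5 h RNA also differed in its 3' bias: the actin control probe sets read 7.81 ± 0.28 higher at the 3' end than at the 5' end at 0 h, and 8.55 ± 0.08 higher at 5 h (log2, SD; two-sided exact permutation p = 0.012). For GAPDH the values were 5.15 ± 0.50 and 5.55 ± 0.08 (exact permutation p = 0.17).

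**Figure D1:**
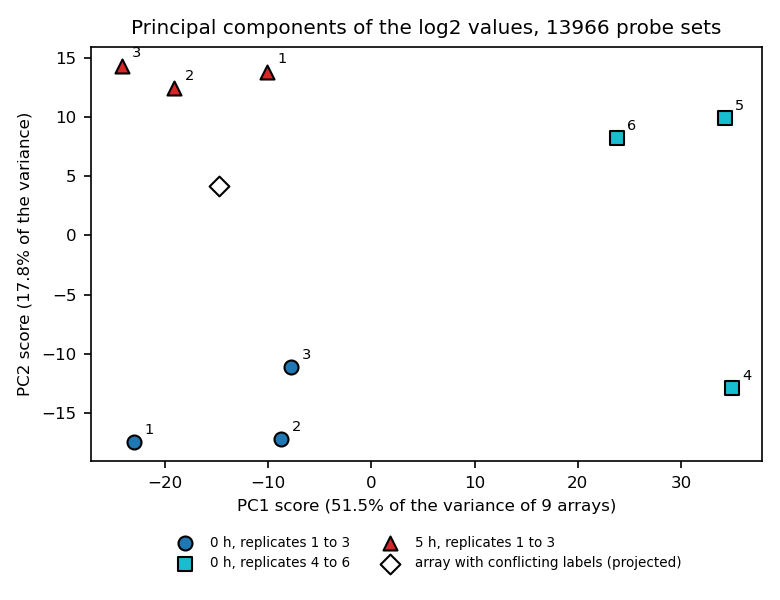
Scores of each array on the first 2 principal components of the log2 values, with symbols for 0 h replicates 1 to 3, 0 h replicates 4 to 6 and the 5 h arrays, replicate numbers beside the points, and the array with conflicting labels projected as an open diamond. The first component held 51.5% of the variance and set 0 h replicates 4 to 6 apart from the other arrays, and the second held 17.8%.

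The comparison of 5 h with 0 h asks which transcripts changed in the first hours after puparium formation in neurons that expressed the dominant negative receptor. Genes changed in both directions. The sugar-splitting enzyme gene Treh rose 4.51-fold, the ecdysone-inducible gene ImpE1 rose 3.07-fold, and the Pax6-type transcription factor gene toy rose 2.09-fold. The stress genes Hsp68 and MtnA fell, reading 3.72-fold and 3.10-fold lower at 5 h. The transcription factor gene Sox14, which is needed for pruning in normal mushroom body neurons, read 1.69-fold lower at 5 h. In all, 174 of 13966 probe sets passed an adjusted p of 0.05 in limma with Benjamini-Hochberg adjustment, 141 higher and 33 lower at 5 h. This balance depended on the setting: repeated quantile normalization gave 153 higher and 101 lower, and a term for 0 h replicates 4 to 6, chosen after the data were seen and setting 5 h against replicates 1 to 3, gave 226 higher and 311 lower. At an unadjusted p of 0.05, 2051 passed.

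The 141 probe sets that rose held 125 different genes named by 1 symbol, and the 33 that fell held 25. The median log2 difference was 0.85 among the higher and -0.76 among the lower, against -0.07 over all probe sets. At least a 2-fold difference was seen for 46 higher and 6 lower probe sets. For all 174, the 6 arrays at 0 h and the 3 at 5 h did not overlap, a separation found in 9.79% of all probe sets and given by chance to 2.38%. Against 0 h replicates 1 to 3 alone 1132 probe sets passed, 610 higher and 522 lower, and against replicates 4 to 6 alone 3077 did, 1750 higher and 1327 lower. Over all probe sets 440 passed in the same direction against both sets, and 41 passed in opposite directions. The 174, which were selected on all 6 arrays at 0 h, were among the 440. Counting the array with conflicting labels as 0 h left 0 probe sets past the limma threshold, with 1693 at an unadjusted p of 0.05, and counting it as 5 h gave 352. With the 3' bias of each array as a covariate 5 probe sets passed, and leaving out the 5 h replicate 3 left 19.

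Among the 10 genes with the largest rises, tpr went from 2.72 ± 0.22 to 5.18 ± 0.34 (log2 signal, SD, n = 6 and n = 3; limma adjusted p = 6.1e-05). Its 0 h mean lay below 3.73, the highest value of the 8 probe sets for sequences foreign to the fly, so its place among the 10 rests on a level in the background; against that value it was at least 2.73-fold higher at 5 h. Treh, which encodes trehalase, the enzyme that splits the blood sugar trehalose into glucose, went from 5.75 ± 0.22 to 7.93 ± 0.13 (adjusted p = 5.1e-05). Jhbp1, named for juvenile hormone binding, rose by 2.13 on the log2 scale with a standard error of 0.21 (adjusted p = 0.0013). Its 0 h mean, 3.74, lay at the background value of 3.73, so the size of its rise is uncertain too. The lipid phosphatase gene wun2 rose by 1.90 ± 0.28 (SE), and bdl, which encodes an immunoglobulin-type membrane protein, by 1.84 ± 0.17 (SE). Cpsf5, a subunit of the factor that cuts messenger RNA before polyadenylation, rose 3.59-fold. The DNA break repair gene mre11 rose 2.87-fold, the dynein light chain gene ctp 2.81-fold (adjusted p = 0.043) and the meiotic checkpoint gene pch2 2.77-fold (adjusted p = 0.041). ImpE1 completed the 10: its brighter probe set went from 4.97 ± 0.37 to 6.59 ± 0.21 (adjusted p = 0.0036), while its other probe set read 4.81 and 4.78. Of the probe sets named only by a CG number, 36 rose and 1 fell. CG4678 rose 3.79-fold and CG11159 rose 2.52-fold, and CG17343 read 1.69-fold lower at 5 h.

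Among the genes that fell, Hsp68, a heat-inducible chaperone, went from 5.81 ± 0.41 at 0 h to 3.92 ± 0.16 at 5 h (log2, SD; limma adjusted p = 0.0021). MtnA, a metallothionein that binds metal ions, went from 10.24 ± 0.17 to 8.60 ± 0.23 (adjusted p = 0.00027). The maltase gene Mal-A5 fell by 1.19 on the log2 scale, and mRpS18A, a mitochondrial ribosomal protein gene, fell by 1.07. The gene ebi fell by 1.03, the small heat shock gene Hsp26 fell by 0.97, and the transporter gene MFS3 fell by 0.91. GstO3, a glutathione transferase gene, read 1.75-fold lower at 5 h. The ribosomal protein gene RpS7 read 1.74-fold lower and the proteasome subunit gene Rpn12 1.73-fold lower.

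**Figure D2:**
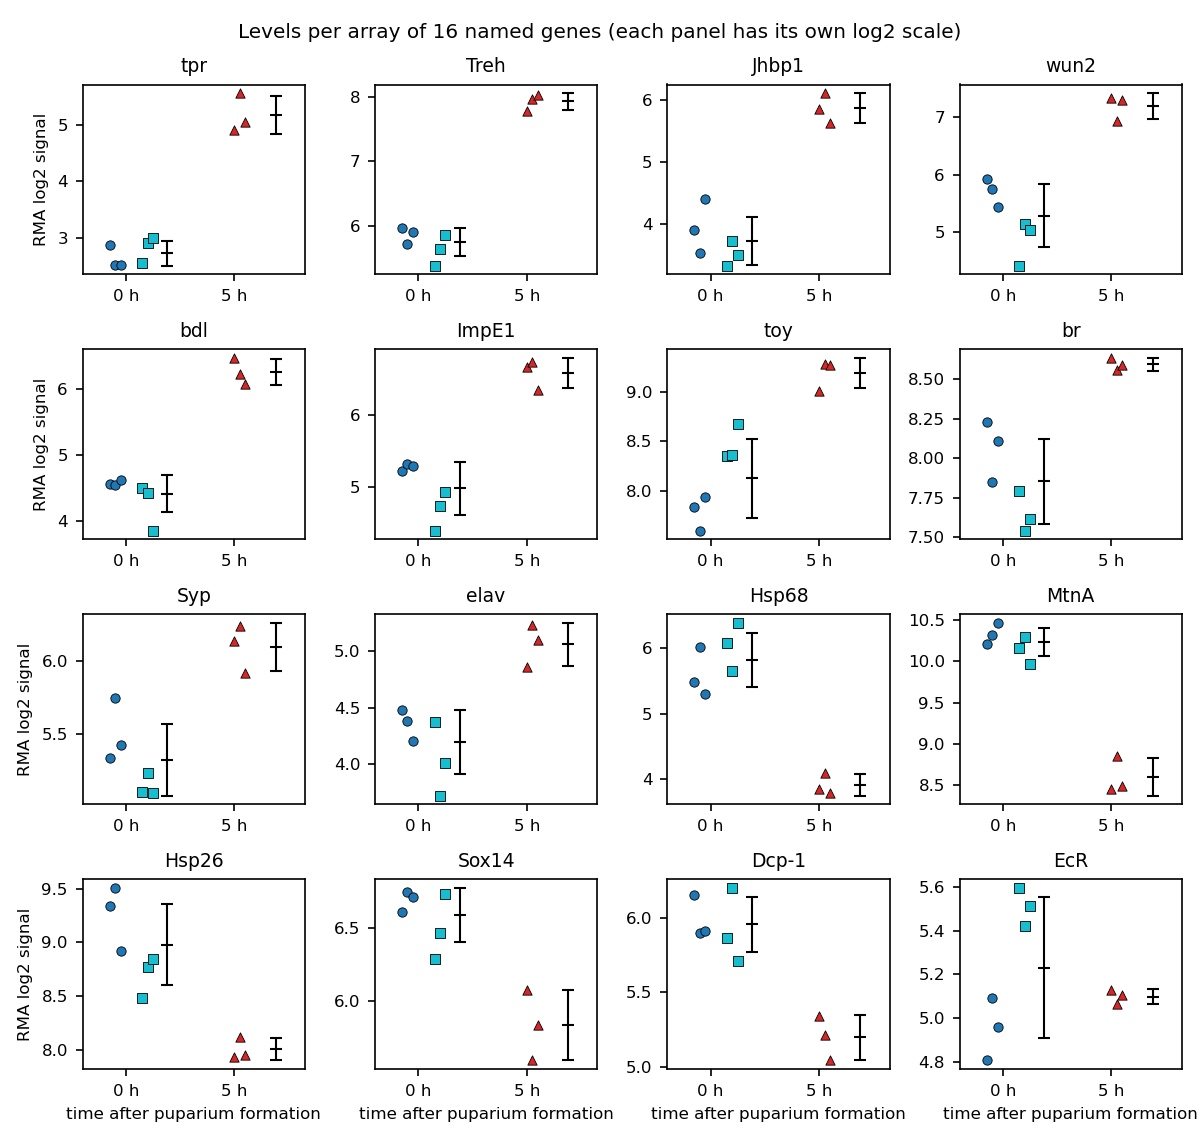
RMA log2 signal per array of 16 named genes at 0 h (circles, replicates 1 to 3; squares, replicates 4 to 6) and at 5 h (triangles), with the mean and SD of each age beside the points; each panel has its own scale. Treh sat at 5.75 ± 0.22 at 0 h and 7.93 ± 0.13 at 5 h, and EcR at 5.23 ± 0.32 and 5.10 ± 0.03.

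Ecdysone response genes went both ways. Of 29 measured, ImpE1 and br rose and Sox14 fell, and 26 did not pass; adjusted over the list alone the counts were also 2 and 1. The gene br, which encodes the Broad zinc finger proteins, went from 7.85 ± 0.27 to 8.59 ± 0.04 in its brightest probe set (limma adjusted p = 0.041); of its other 2 probe sets 1 read -0.05 on the log2 scale, 5 h minus 0 h, and 1 lay below the background value of 3.73 at both ages. Sox14 went from 6.59 ± 0.18 to 5.83 ± 0.24 (adjusted p = 0.028). In the list 22 genes read lower at 5 h, the median was -0.17, and camera did not separate the list from other genes (adjusted p = 0.36). The mixed p of fry, which asks whether members differ in either direction, passed (adjusted p = 0.00011), as it did in 13 of the 24 lists tested; the directional p of fry did not (adjusted p = 0.21). Of 43 genes tied to axon pruning, the cell adhesion gene Nrg rose 1.66-fold (adjusted p = 0.021), Sox14 fell, and 41 did not pass (list median 0.016, camera adjusted p = 0.64, mixed fry adjusted p = 0.074). Adjusted over the list alone, 3 rose and 1 fell. The activin and BMP list holds some receptors that act upstream of EcR in these neurons. None of its 17 genes passed over all probe sets and 1 rose adjusted over the list alone. The gene sax read 0.68 higher (limma adjusted p = 0.082) and Med 0.51 higher (adjusted p = 0.14), and camera gave an adjusted p of 0.40.

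The mushroom body, pan-neuronal and cytoskeletal lists lay above other genes at 5 h in camera with its preset correlation, and none did with an estimated correlation (adjusted p = 0.24, 0.24 and 0.42). The glia list (mean 0.33) and the 3' bias of actin (7.81 at 0 h and 8.55 at 5 h) were also higher at 5 h, so these calls do not separate neurons from glia or from RNA quality. Of 20 mushroom body neuron genes, 3 rose and none fell: toy by 1.06 ± 0.21 (log2, SE; limma adjusted p = 0.038), br, and 14-3-3zeta, a signalling adaptor used in olfactory learning, by 0.66 ± 0.12 (SE; adjusted p = 0.025). Adjusted over the list alone 4 rose. The list passed camera with its preset correlation (median 0.11, adjusted p = 0.027), with an adjusted p = 0.24 with an estimated correlation. Of 24 pan-neuronal and synaptic genes, the RNA-binding protein gene elav rose 1.82-fold (adjusted p = 0.033) and 3 rose adjusted over the list alone; camera gave an adjusted p of 0.027, and 0.24 with an estimated correlation. Among 25 genes for actin and microtubules, alphaTub84D, an alpha tubulin gene, rose in both of its probe sets, by 0.73 and 0.67 (log2), and 3 rose adjusted over the list alone. That list's median was 0.15 (camera adjusted p = 0.027, and 0.42 with an estimated correlation). Of 28 RNA-binding regulators elav and Syp rose, Syp from 5.33 ± 0.25 to 6.10 ± 0.16 (adjusted p = 0.034), and 3 rose adjusted over the list alone (camera adjusted p = 0.37). Of 34 genes for axon guidance and adhesion Nrg rose, with 4 adjusted over the list alone (camera adjusted p = 0.66).

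Genes of dividing cells were also measured, since neuroblasts lie close to the captured neurons. None of 31 cell cycle genes passed alone, over all probe sets or over the list, yet 21 read higher at 5 h and the list passed camera (median 0.19, adjusted p = 0.012; adjusted p = 0.42 with an estimated correlation). The glia list and the 3' bias of actin were higher at 5 h as well, and with the 3' bias as a covariate the cell cycle list no longer passed (median 0.07, camera adjusted p = 0.065). Mcm5, a subunit of the replicative helicase, read 4.51 ± 0.29 and 5.14 ± 0.36 (limma adjusted p = 0.15), and the mitotic kinesin gene Klp61F 5.48 ± 0.15 and 6.03 ± 0.34 (adjusted p = 0.10). Of 21 neuroblast and ganglion mother cell genes only Syp rose, with 2 adjusted over the list alone, and camera gave an adjusted p of 0.78.

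In the stress and proteasome lists the genes that passed over all probe sets fell. Of 13 heat shock and chaperone genes, Hsp68 and Hsp26 fell and none rose; adjusted over the list alone, 5 fell and 1 rose. The median was -0.36 (camera adjusted p = 0.027, and 0.42 with an estimated correlation). With the 3' bias as a covariate the heat shock list no longer passed (median -0.30, camera adjusted p = 0.22). It passed camera against 0 h replicates 1 to 3 (adjusted p = 0.0018) and not against replicates 4 to 6 (adjusted p = 0.17). Of 44 ubiquitin and proteasome genes Rpn12 and Rpn1 fell, Rpn1 from 7.94 ± 0.13 to 7.39 ± 0.11 (limma adjusted p = 0.039), and adjusted over the list alone 2 fell and 1 rose. The proteasome list's median was 0.09 (camera adjusted p = 0.64); it was -0.24 against 0 h replicates 1 to 3 (adjusted p = 8.1e-05) and 0.27 against replicates 4 to 6 (adjusted p = 0.0011), so the direction turned with the 0 h arrays used. Of 17 apoptosis genes Debcl, a Bcl-2 family gene, rose 2.44-fold (adjusted p = 0.044) and the effector caspase gene Dcp-1 read 1.69-fold lower at 5 h (adjusted p = 0.020); adjusted over the list alone, 2 rose and 1 fell (camera adjusted p = 0.99). None of 24 autophagy genes passed, over all probe sets or over the list (camera adjusted p = 0.66). Vps15 read 0.59 higher and Atg12 -0.51, with limma adjusted p of 0.23 and 0.26. The 5 h mean of Atg12, 3.56, lay below the background value of 3.73.

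Of 37 cytosolic ribosomal protein genes RpS7 and RpL28 fell, RpL28 from 7.50 ± 0.13 to 6.97 ± 0.10 (limma adjusted p = 0.041), with 3 adjusted over the list alone (camera adjusted p = 0.40). Of 64 mitochondrial ribosomal protein genes mRpS25 rose 2.19-fold and mRpS18A fell, and adjusted over the list alone 4 rose and 3 fell (camera adjusted p = 0.70). Of 73 oxidative phosphorylation genes the complex I subunit gene ND-MNLL rose, by 0.74 in 1 of its probe sets and with 0.22 in the other, which did not pass; the count adjusted over the list alone was also 1 (camera adjusted p = 0.70). These 3 lists depended on the 0 h arrays used. Against replicates 1 to 3 each passed camera as lower, with adjusted p of 0.00023 for cytosolic ribosomal proteins, 8.1e-05 for mitochondrial ribosomal proteins and 0.0067 for oxidative phosphorylation. Against replicates 4 to 6 the camera direction was upward in each and none passed (adjusted p = 0.57, 0.17 and 0.34). After repeated quantile normalization of all 9 arrays each passed as lower.

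Markers of other cells that a capture could hold were measured in the same way. Of 24 glial genes bdl, wun2 and nrv2, a sodium pump subunit gene, rose, nrv2 from 4.22 ± 0.41 to 5.50 ± 0.06 (limma adjusted p = 0.018). Adjusted over the list alone 4 rose. The glia list passed camera with a median of only 0.07 and a mean of 0.33 (adjusted p = 0.048, and 0.24 with an estimated correlation). Of 19 epidermis and cuticle genes none passed alone, over all probe sets or over the list, and 18 read lower at 5 h (median -0.19, camera adjusted p = 0.040, and 0.42 with an estimated correlation); verm read -0.64 on the log2 scale, 5 h minus 0 h, and Gasp had means below the background value at both ages (3.04 and 2.62). Of 19 muscle genes bt, which encodes the giant sarcomere protein projectin, rose by 1.06 in 1 probe set, while the other lay below the background value of 3.73 at both ages; 1 rose adjusted over the list alone (camera adjusted p = 0.70). None of 20 salivary gland genes passed (camera adjusted p = 0.073). Eig71Ea read 4.43 ± 2.79 and 2.80 ± 0.02, and Eig71Eg 3.89 ± 1.72 and 2.78 ± 0.13. Both had 5 h means below the background value. Their 0 h means rested largely on 1 array, 0 h replicate 2, which read 10.01 and 7.37. None of 13 fat body genes passed (camera adjusted p = 0.71); Fbp2 read 8.11 ± 1.70 and 6.97 ± 0.89, and apolpp 8.81 ± 0.52 and 9.64 ± 0.27. None of 15 hemocyte genes passed over all probe sets and 1 rose adjusted over the list alone (camera adjusted p = 0.78). The gene crq read 3.68 ± 0.64 and 5.08 ± 0.30 (limma adjusted p = 0.063), with its 0 h mean below the background value. Pxn read 6.26 ± 0.30 and 6.65 ± 0.27. None of 16 retina and photoreceptor genes passed (camera adjusted p = 0.97); rdgA read -0.24, 5 h minus 0 h, and trp lay below the background value at both ages (2.77 and 2.92). Of the sex dosage markers 2 were measured, too few to test as a list, and Sxl read -0.07 and msl-2 -0.05.

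**Figure D3:**
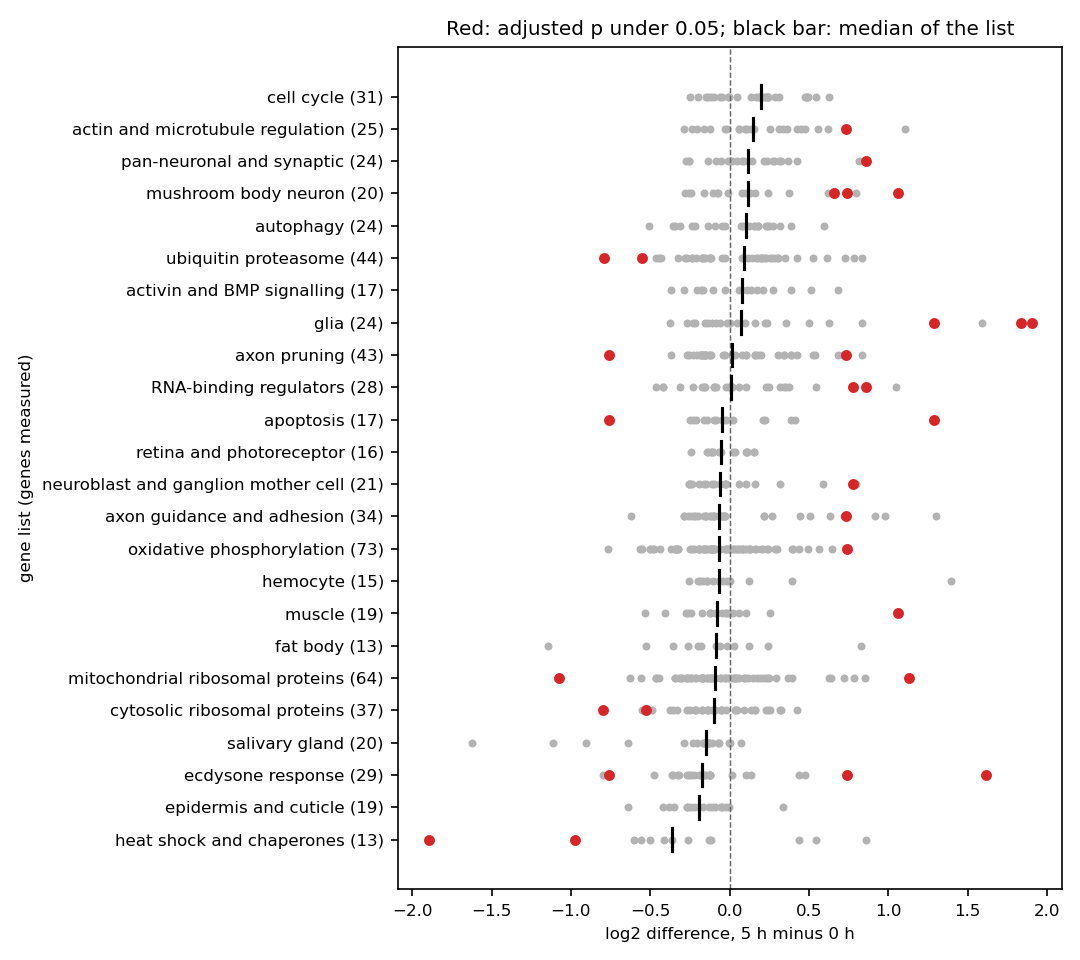
Log2 difference, 5 h minus 0 h, of each measured gene (points) in 24 lists, with the number of genes measured in brackets; red points passed an adjusted p of 0.05 over all probe sets and the black bar is the list's median. The heat shock and chaperone list had the lowest median, -0.36, and the cell cycle list the highest, 0.19.

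In all, 7 of the 24 lists tested passed camera with its preset correlation, 0 passed with an estimated one, and 3 of the 7 passed the directional p of fry, the mushroom body, pan-neuronal and glia lists. Of the 7, 4 passed against 0 h replicates 1 to 3 alone, 1 passed against replicates 4 to 6 alone, and none passed against both. Median and mean had opposite signs in the apoptosis (-0.05 and 0.03), neuroblast (-0.06 and 0.04), hemocyte (-0.07 and 0.03) and axon guidance (-0.06 and 0.10) lists. The retina list had a median of -0.06 with an upward camera direction. As single measures, the mean level of the mushroom body neuron list was 6.01 ± 0.07 at 0 h and 6.23 ± 0.003 at 5 h, that of the pan-neuronal list 5.59 ± 0.05 and 5.76 ± 0.02, and that of the glia list 4.75 ± 0.14 and 5.09 ± 0.05 (log2, SD, n = 6 and n = 3). Over the 10 cell type lists their two-sided exact permutation p, adjusted with Benjamini-Hochberg, was 0.060, 0.060 and 0.079; the smallest adjusted value among the others was 0.089, for the epidermis and cuticle list.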

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

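Several tests below were chosen after the results were seen. Among these were the tests of the split within the 0 h arrays on the glial and the stress genes. So were those of the handling of the 0 h animals and of the 3' bias and the cell types of 0 h replicates 4 to 6. The bound over all 15 glial genes was also added then. The others are recorded as chosen before. Those on named genes or on the 0 h split still address patterns that the results had already shown. Single arrays that stood apart from the rest of their group were sought among 88 levels and measures of the 6 arrays at 0 h, where chance alone marks about 1 in 20.

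Among the 84 splits of the 9 arrays into 6 and 3, 3 gave at least the 174 probe sets of the real split, the real one included, a share under 0.05. The other 2 set apart 0 h replicates 4 to 6, with 4647 probe sets, and 0 h replicates 1 to 3, with 200, while 79 splits gave 0. The share thus shows that the arrays fall into sets of 3. It cannot tell age from any other difference that the 5 h arrays share. Against 0 h replicates 1 to 3 alone the real count was 1132 and the highest of the other splits 0, but the 10 splits of 6 arrays are too few for a share under 0.05. For gene lists chance is not excluded: 16 of the 84 splits gave at least the real 7 lists, and the highest of the others gave 11.

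The 0 h arrays themselves form a pattern: replicates 4 to 6 differed from replicates 1 to 3 in 2464 probe sets in limma, 907 higher and 1557 lower, a split that was read from the data and so is described, not tested, by this count. The SD of all log2 values was 1.53 ± 0.05 in replicates 4 to 6 and 1.70 ± 0.04 in 1 to 3, but a narrower signal range as the whole cause is argued against, since 59.2% of these probe sets still differed after all 6 arrays were put on 1 distribution. It may be part of the cause, which was not tested. The difference fell with the mean level across probe sets (Pearson r = -0.43), and on 1 distribution r was -0.022. Neither value adds support: the first restates the difference between the SDs, and putting the arrays on 1 distribution removes that difference. A stronger 3' bias of replicates 4 to 6 cannot be told apart from the rest: the actin difference was -0.21 on the log2 scale and that of GAPDH 0.70, on 3 arrays each. A smaller share of mushroom body neurons in replicates 4 to 6 cannot be told apart either. On 1 distribution the glia list read -0.24 (95% bounds adjusted for 8 lists, -0.58 and 0.10) and the muscle list 0.27 (-0.07 and 0.60), replicates 4 to 6 minus 1 to 3, and the mushroom body list 0.09. As deposited, replicates 1 to 3 and 4 to 6 read 4.87 ± 0.06 and 4.63 ± 0.07 for glia. For muscle they read 4.34 ± 0.03 and 4.63 ± 0.06. The mean of the 2 sex dosage markers was 4.43 ± 0.02 and 4.80 ± 0.09. That mean does not keep Sxl and msl-2 apart, so it cannot show a shift between the sexes. In single arrays Sxl read 4.99 to 5.07 and 5.31 to 5.49, and msl-2 read 3.74 to 3.91 and 3.89 to 4.37. A different mixture of other cells or of sexes was not tested and stays open. A different collection, amplification or hybridisation batch could lie behind the split and stays open, as no label names one; no biological explanation was tested, as the labels give none.

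Another pattern is the rise of the glial genes bdl, wun2 and nrv2 at 5 h. With the 3' bias as a covariate their median log2 difference was 2.05. The gene wun2 went from 1.90 to 2.42, with a 95% interval of 1.47 to 3.37, and nrv2 from 1.28 to 1.76, with 1.06 to 2.46. Both lost their calls (limma adjusted p = 0.14) through the wider error, not a smaller difference. These values cannot decide whether the 3' bias is the source, as the covariate overlaps with age. The mean of the actin and GAPDH differences was 6.98 to 7.10 in the 5 h arrays and 6.16 to 6.78 in the 0 h arrays. The split within 0 h cannot be weighed with these genes, which were picked from the called probe sets. Of the 174 called, 171 kept their call with a term for the split, so passing was nearly fixed. With that term bdl read 1.68, wun2 1.48 and nrv2 0.99 higher against replicates 1 to 3 (limma adjusted p = 0.00030, 0.0015 and 0.0057). The 95% interval of the smallest was 0.63 to 1.34, and each read higher still against replicates 4 to 6. The selection fixed the sign of these values and favoured large ones, so their sizes and the interval may be too high. More glial tissue in the 5 h captures cannot be told apart from a change within these cells: the 12 other glial genes at levels between 3.73 and 6 had a median of 0.023 (95% bootstrap bounds -0.09 and 0.43), but that prediction left out the genes that rose, and over all 15 the upper bound was 1.28. Of the 12, 6 read higher at 5 h, with alrm the highest at 1.59 (limma adjusted p = 0.15). The glial gene repo, outside that level window, read 0.83 (adjusted p = 0.25). Both were named after their values were seen. A larger share of some glia may contribute, and the age of the animals remains an untested alternative.

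The remaining pattern is the fall of the stress genes Hsp68, Hsp26 and MtnA. The split within 0 h cannot be weighed with these genes either, as they too were picked from the called probe sets. With a term for it Hsp68 read -1.68, Hsp26 -1.25 and MtnA -1.73 against replicates 1 to 3 (adjusted p = 0.0012, 0.0012 and 7.0e-05), and the value closest to 0 against either set was -0.70, for Hsp26 against replicates 4 to 6 (95% interval -1.03 to -0.36; adjusted p = 0.0067). The 3' bias cannot be told apart from age for all 3: with it as a covariate the median was -1.70, MtnA went from -1.63 to -1.70 and kept its call, Hsp68 went from -1.90 to -1.80 (95% interval -2.61 to -0.99) and lost its call through the wider error, and Hsp26 went from -0.97 to -0.47 (-1.10 to 0.15) and lost its call through both. Different handling of the 0 h animals may also have raised these genes at 0 h and cannot be told apart from age, since the labels say of collection only that animals at 0 h were taken as white pupae. The 11 other heat shock and chaperone genes had a median of -0.26, with bounds of -0.50 and 0.44, 8 of them below 0.

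The level of bdl in 0 h replicate 6 was 3.86, against 4.42 to 4.63 in the other 5 arrays at 0 h. Gasp read 4.26 in 0 h replicate 1, against 2.50 to 2.99 in the others. In 0 h replicate 2 Eig71Ea read 10.01 (2.89 to 4.42 in the others), Eig71Eg read 7.37 (2.96 to 3.63) and the mean level of the salivary gland list was 4.51 (3.46 to 3.64). The level of alphaTub84D in 0 h replicate 4 was 11.92, against 12.39 to 12.59 elsewhere at 0 h. The mean level of the retina and photoreceptor list in 0 h replicate 6 was 4.31, against 4.12 to 4.19 in the others.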

How the results depend on the processing

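The settings that use only part of the 0 h arrays or a term for their split were chosen after seeing the data; all others were planned. The number of 174 changed probe sets did not hold. The array with conflicting labels gave 0 changed (0 higher, 0 lower) as 0 h, with 1693 at an unadjusted p of 0.05, and 352 (295 higher, 57 lower) with 4 gene lists as 5 h, where 161 of the 174 remained. Array weights gave 1809 (1106 and 703) with 4 lists, all 174 among them; repeated quantile normalization gave 101 lower, against 153 higher; median centring gave 20 lower and 140 higher; a trended and robust prior gave 21 lower. An adjusted p of 0.01 left 32 (26 and 6) and 0 lists, and at least a 2-fold difference left 52 (46 and 6), by construction. The exact permutation test per probe set gave 0, 0 and 0: its smallest adjusted p, 0.28, cannot reach the threshold, and 1743 probe sets had an unadjusted p under 0.05. With the 3' bias as a covariate 5 (4 and 1) and 3 lists passed. The lists were those of glia, of actin and microtubules, and of ubiquitin and the proteasome. The last did not pass in the main setting and was here called higher (median 0.35, camera adjusted p = 0.0039). Only 0 h replicates 1 to 3 gave 1132 (610 and 522). Only replicates 4 to 6 gave 3077 (1750 and 1327) with 2 lists, and a term for the split gave 537 (226 and 311). The ubiquitin and proteasome list turned to a median of -0.24, called lower, with replicates 1 to 3, the split term or the description block. These settings estimate the same difference, that of 5 h from 0 h replicates 1 to 3. Leaving out 1 array moved the count from 19 (without 5 h replicate 3) to 395 (without 0 h replicate 1), with 98 and 105 without 0 h replicates 2 and 3 and 47 and 27 without 5 h replicates 1 and 2; higher calls ran from 14 to 347, lower calls from 5 to 54, and lists from 0 (without 5 h replicate 1) to 8.

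Gene list calls fell to 3 for probe sets above the median level, 1 above a log2 level of 5, 1 with the mean of a gene's probe sets, 0 with an estimated correlation and 3 with the directional p of fry; the mixed p of fry gave 13. In each of these settings the cause was not tested, beyond the fewer genes that the filters left. The ecdysone response list (median -0.17) passed with the mixed p of fry (adjusted p = 0.00011), which counts differences in either direction, and in no other setting; the axon pruning list passed in none. As a replicate block, the numbers of the descriptions gave 743 (393 and 350) and those of the titles 6 (5 and 1). A 0 h array without a same-numbered 5 h array adds nothing to the difference in such a fit. The description block thus again set 5 h against 0 h replicates 1 to 3, and the title block set it against 0 h replicates 2 to 4. Same-numbered arrays did not deviate together (r across probe sets of -0.40, 0.005 and 0.22 by description, -0.21, 0.14 and -0.34 by title). Not every array correlated best with its own number. The deviations at 0 h were taken from the mean of all 0 h arrays and hold the split between them. They therefore cannot decide whether same-numbered arrays share more than a number. Signal over background limits the lowest levels: 8 of the 141 higher probe sets had a 0 h mean below the highest foreign control value.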

Other observations

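The genes named in this part were chosen after their values were seen, and those said to rise or fall passed the limma test over all probe sets. Genes that no fixed list held also rose at 5 h: nAChRbeta1, an acetylcholine receptor subunit, by 0.88 on the log2 scale (adjusted p = 0.017), the dopamine transporter gene DAT by 1.02 (adjusted p = 0.0036), the G protein gene Galphaq by 0.85 (adjusted p = 0.049) and the potassium channel gene Irk2 by 0.86 (adjusted p = 0.011). Unc-76, a kinesin adaptor used in axonal transport, rose by 1.10 (adjusted p = 0.0054), and the splicing regulator gene Rbfox1 by 0.69 (adjusted p = 0.039). For all of them the 3 arrays at 5 h lay above all 6 at 0 h. That adds no support, as the ages did not overlap in any of the 174 called probe sets. With a term for the split within 0 h Galphaq read 0.66 and did not pass (limma adjusted p = 0.056).

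The histone demethylase gene Kdm5 rose by 1.15 (adjusted p = 0.022), the corepressor gene gro by 0.70 (adjusted p = 0.010) and the chromatin repressor gene l(3)mbt by 0.87 (adjusted p = 0.049). The Notch-modifying glycosyltransferase gene fng rose by 1.01 (adjusted p = 0.024), and Sdc, which encodes the heparan sulphate proteoglycan syndecan, by 0.64 (adjusted p = 0.018). Among the lower genes outside the lists, the proteasome-bound deubiquitinase gene Usp14 fell by 0.45 (adjusted p = 0.043) and the glycolytic gene Pglym78 fell by 0.66 (adjusted p = 0.027).

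The array with conflicting labels, which belongs to no group here, was read against both ages as values only. Of the 174 probe sets past the threshold, it lay nearer to the 0 h mean for 54 and nearer to the 5 h mean for 120, with a median position of 0.64 on a scale from 0 (the 0 h mean) to 1 (the 5 h mean). Its log2 level of wun2 was 7.16, of bdl 6.27, of Treh 7.61, of Hsp68 3.82 and of MtnA 8.77. Its level of elav was 4.02, of 14-3-3zeta 10.10, of toy 8.44, of br 8.18 and of EcR 4.96. Its 3' minus 5' difference was 8.44 for actin and 5.91 for GAPDH. Across all probe sets its Pearson r was 0.991 with each 5 h array. The r was 0.983 to 0.989 with 0 h replicates 1 to 3, and 0.957 to 0.970 with 0 h replicates 4 to 6.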
